A study of Homo with 6 samples.

How the data were processed

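Gene expression was measured by bulk RNA sequencing in AGS cells, an established line of human gastric adenocarcinoma. Per the labels, all 6 libraries came from cells incubated with GM-CSF, a cytokine that drives the growth of myeloid cells. In 3 of them the cells carried siNC, the control small interfering RNA, and in 3 they carried siAPE1, directed at APE1, an endonuclease of base excision repair encoded by APEX1. Per the labels' protocols, total RNA was extracted with Trizol, polyadenylated RNA was captured with oligo beads and libraries were sequenced on an MGISEQ-T7 instrument. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

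The submitters' processing notes name the aligner HISAT2 and the genome builds GRCm39, mm39 and hg18. The first 2 names belong to the mouse and the third to an old human build, and the role of each is not given in the sources used here. The counting tool, the annotation and any filter are not given in the sources used here either. The values the authors deposited were read as TPM (reads divided by feature length and scaled to the same total in each library). Neither header nor labels name the unit, and this reading was worked out from the digits. Each value equalled a whole number of reads times a constant of its library divided by a whole number of bases. The relative tolerance was 1e-09 plus a term that grew as the value fell, so a match says less for low values. Such a pair of reads and length was found for all 19328 features above 0 in at least 1 library, which is 100% of them. Where all reads and the length share a common factor the smallest solution was taken. On a simulated table of 5904 features the same procedure returned the exact reads for 98.9% of them. FPKM was excluded because its constant would require a library total that is not a whole number and is smaller than the sum of the recovered reads. Another scaling of reads over length by a constant of each library would leave the same pattern and was not excluded. The listed features summed to between 43.9% and 47.7% of the total to which TPM is scaled. If the values are TPM, the authors' scaling ran over more features than were analysed here.

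The table has 1 column per library, named by the letter C or T and a number. C was read as control (siNC), T as treated (siAPE1) and the number as the replicate. No label states this reading of the letters, and no measurement here could check it, for the reason that follows. Every direction given below depends on it.

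Each feature carries an Ensembl gene identifier. The gene table used here held 0 Ensembl identifiers, so no symbol could be looked up. That says nothing about the identifiers themselves. The identifiers were tested against an excerpt of GENCODE release 29 on human chromosome 1 that comes with pyranges 0.1.4. Of 34 identifiers found in both, 23 had reads in at least 3 libraries. The length recovered from their TPM values lay within 20% of the exonic length of the gene in 4 cases, against a mean of 2.64 cases when the lengths were shuffled. Features are therefore treated as unnamed, identifiers are not printed, and a feature is referred to by its recovered length. The level of APEX1, the 27 gene lists fixed before the data were examined and the markers of other cell types were not analysed here, because each of them needs names.

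Tests were made on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend, robust moderation and group as the only term, over all 6 libraries. Features of at least 1 TPM in at least 3 libraries were tested, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes on this scale understate the change of low features. The design had foreseen a count model for a table of counts and this test for a table of normalized values. The rule for named genes, fixed before the data were examined, took the largest changes among features past the threshold with a mean of at least 5 TPM and no overlap between groups. It passed over any gene without a symbol, and no symbol could be looked up here, so it named none. After the data were seen, the symbol condition was dropped and 2 features each way were taken. The 5 most abundant called features each way, also with no overlap between groups, were added after the values were seen. In groups of 3 against 3 an exact permutation test cannot give a two-sided p under 0.1.

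The test was also run on simulated data. In 20 simulations of the 9596 tested features, with a biological coefficient of variation of 0.15 and 200 changed features, it recovered 9.33% of features changed 1.5-fold, 61.6% of those changed 2-fold and 90.2% of those changed 4-fold. In those simulations 8.11% of calls were false, more than the nominal 5%. The real data gave 2547 calls, so the Benjamini-Hochberg threshold was less strict in them than with 200 changed features. These shares therefore need not carry over to the real data. Alternatives were the replicate number as a block, other pseudocounts, no filter on low values, quantile normalization, a test against a 1.5-fold change, and the omission of each library. Equal medians, removal of a length trend and limma-voom on the recovered reads were added after the data were seen. Recovered reads per library ranged from 9313464 to 11189954 over the listed features. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.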

Results

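RNA from AGS gastric adenocarcinoma cells was sequenced in 6 libraries, 3 from cells given the control siRNA (siNC) and 3 from cells given siAPE1. Cells of both groups were incubated with GM-CSF, so the effect of GM-CSF itself was not tested. The table listed 20263 features, of which 935 were at 0 in all 6 libraries and 10872 were above 0 in all 6. Reads recovered from the TPM values came to 9420518, 11189954 and 10079760 in siNC replicates 1, 2 and 3 and to 10226432, 9313464 and 9466104 in siAPE1 replicates 1, 2 and 3. Totals did not separate the groups (exact permutation test, two-sided p = 0.6, n = 3 per group, smallest possible p 0.1).

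In the part that could be examined, on chromosome 1, the identifiers in the table did not follow the values they stood beside. Over 23 identifiers with a known exonic length, the length behind the TPM values and the exonic length had a Spearman coefficient of 0.154 (permutation test across genes, two-sided p = 0.482) and a Pearson coefficient of 0.0794 on log lengths (p = 0.717, permutation test). Genes are not independent replicates, and these p-values describe the pairing alone. Within a pair the longer length exceeded the shorter by a median of 2.18 times and by up to 28.9 times. Features are accordingly described by length, level and change, without gene names. The knockdown of APEX1 was not checked here, so the groups rest on the labels and on the reading of the column letters as control and treated.

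**Figure D1:**
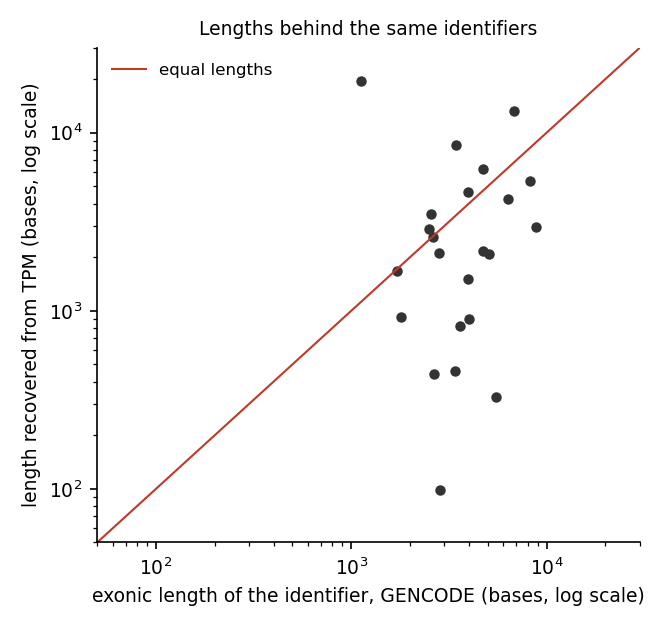
Length recovered from TPM against exonic length in GENCODE, both in bases on log axes, for 23 identifiers with reads in at least 3 libraries. Each point is 1 identifier and the line marks equal lengths, and 4 points lie within 20% of the line.

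The design asks how the transcriptome of GM-CSF-incubated AGS cells differs after siAPE1. Of 9596 tested features, 1717 were higher and 830 were lower in siAPE1 than in siNC (limma, Benjamini-Hochberg adjusted p under 0.05), together 26.5% of those tested. The other 7049 did not pass the threshold. The median change was 0.70 on the log2 scale among higher features (quartiles 0.53 and 0.97) and -0.70 among lower features (quartiles -0.97 and -0.51), with a median standard error of 0.16 over the tested features. A change of at least 2-fold was found for 400 higher and 191 lower features, and of at least 4-fold for 30 and 19. The 3 values of one group all lay above the 3 of the other in 46.7% of tested features, against 10% by chance. No feature had at least 10 reads in each library of one group and 0 in all libraries of the other.

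Higher features made up 67.4% of the calls. The median log2 change of all tested features was 0.13, so changes are measured against a scale on which the middle feature was itself higher in siAPE1. Without siNC replicate 2 this median was 0.08. With the medians of the libraries made equal, 1137 features were higher and 1235 lower, which put the share of higher calls at 47.9%. That share was 49.5% after quantile normalization and 51.5% with limma-voom on the recovered reads. The higher features held 12.8% ± 0.767 of the listed TPM in siNC and 21.2% ± 0.719 in siAPE1 (SD, n = 3), and the lower features held 17.8% ± 0.313 and 10.8% ± 0.206. These shares describe features that had been selected for their difference. Omitting siAPE1 replicate 1, 2 or 3 left 979, 789 or 731 higher and 494, 398 or 393 lower features. Omitting siNC replicate 1 left 483 lower features.

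**Figure D2:**
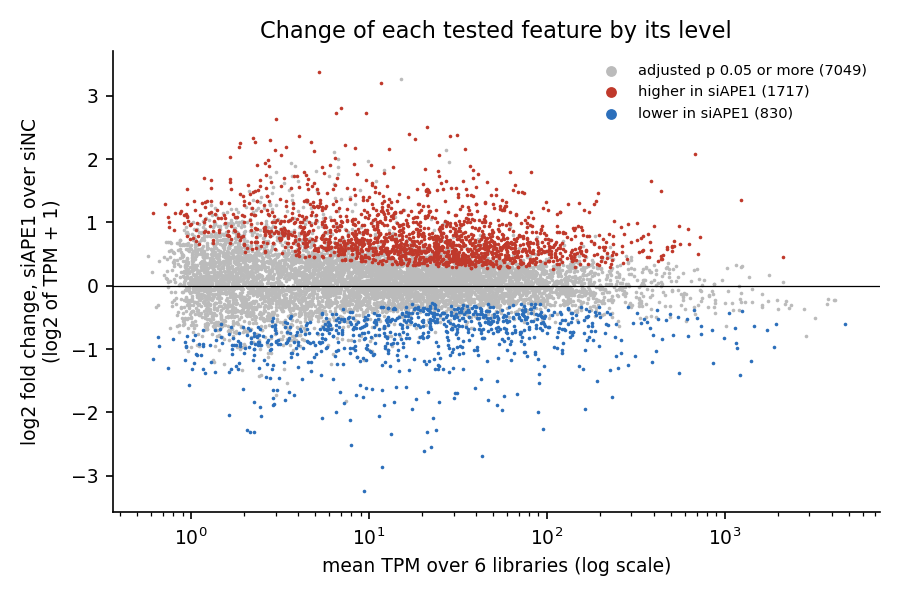
Log2 fold change of siAPE1 over siNC, computed on log2(TPM + 1), against mean TPM over the 6 libraries on a log axis. Each point is 1 of 9596 tested features, with the 1717 higher features in red, the 830 lower in blue and the other 7049 in grey.

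Among abundant features, one of 4849 bases rose from 260.5 ± 10.02 TPM in siNC to 1105 ± 32.2 TPM in siAPE1 (SD, n = 3 per group). Its means differed 4.24-fold (log2 fold change 2.08, standard error 0.09, limma adjusted p = 0.00019). A feature of 2980 bases rose from 698 ± 51.4 to 1779 ± 36.6 TPM, a difference of 2.55-fold (log2 fold change 1.35, standard error 0.10, limma adjusted p = 0.000385). Both passed the threshold in all 15 alternatives. The other 3 of the 5 most abundant higher features had lengths of 3018, 6530 and 1963 bases, with means 1.38, 1.70 and 1.42 times as high in siAPE1 as in siNC. Among lower features, the most abundant had 4133 bases and fell from 5738 ± 420 to 3760 ± 242 TPM (log2 fold change -0.61, standard error 0.12, limma adjusted p = 0.0119). Its call was lost under quantile normalization (log2 fold change -0.13, adjusted p = 0.276), in the test against a 1.5-fold change (adjusted p = 1) and without siAPE1 replicate 2 or 3 (adjusted p = 0.0659 and 0.0737). A feature of 1623 bases fell from 2518 ± 520 to 1282 ± 174 TPM (log2 fold change -0.96, standard error 0.18, limma adjusted p = 0.00963). The remaining 3, of 2004, 860 and 2118 bases, had means 1.53, 1.63 and 1.56 times as high in siNC as in siAPE1. The call was lost in 10 of 15 alternatives for the 3018-base feature, in 7 for the 2004-base feature and in 5 each for the 1963-base and 860-base features. It was lost in 2 for the 2118-base feature and in 1 each for the 1623-base and 6530-base features. These 10 features were chosen after their values were seen.

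**Figure D3:**
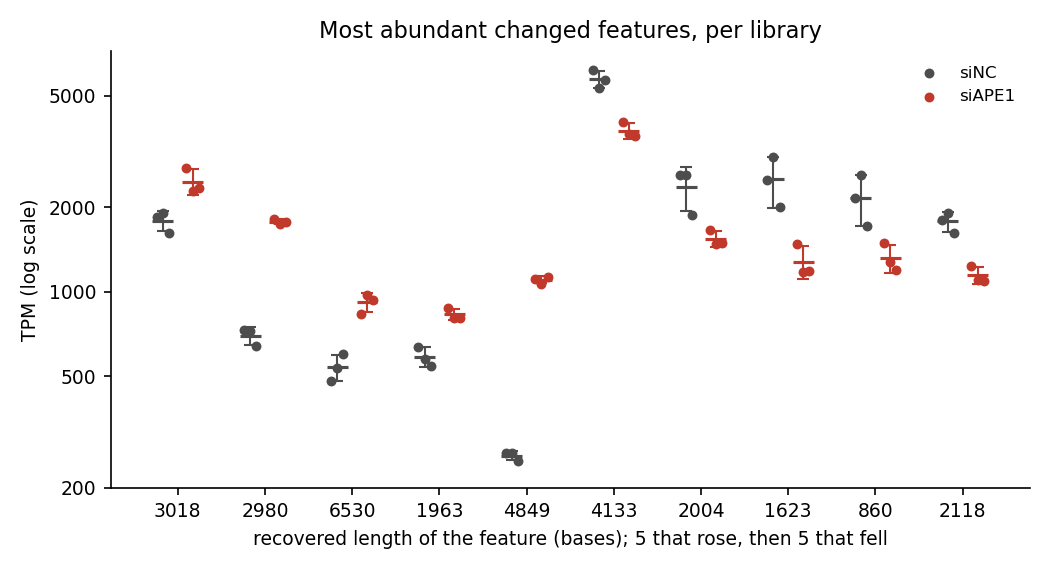
TPM on a log axis of the 5 most abundant features that were higher and the 5 that were lower in siAPE1, by recovered length in bases. Dots are the 3 libraries of each group, horizontal lines the means and bars the SD. Features were taken only if the 3 siAPE1 values lay on one side of the 3 siNC values.

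The rule fixed before the data were examined required a symbol and named no feature, because no symbol could be looked up. Dropping that condition after the data were seen, and taking 2 features each way, the largest fall belonged to a feature of 2488 bases, which went from 17.7 ± 1.88 TPM in siNC to 1.11 ± 1.01 TPM in siAPE1 (SD, n = 3). Its log2 fold change was -3.25 with a standard error of 0.31 (limma adjusted p = 0.000808). It was followed by a feature of 2291 bases, which went from 21.6 ± 0.259 to 2.21 ± 1.003 TPM (log2 fold change -2.86, standard error 0.21, limma adjusted p = 0.000347). Both passed the threshold in all 15 alternatives, in which the log2 fold change ranged from -4.50 to -1.90 for the 2488-base feature and from -3.47 to -1.89 for the 2291-base feature. The largest rises belonged to very short features with few reads. One of 74 bases had 0 reads in every siNC library and 2, 6 and 3 reads in siAPE1 replicates 1, 2 and 3. Its limma adjusted p was 0.00121. Its highest adjusted p in the 15 alternatives was 0.028, from limma-voom on the recovered reads. Its siAPE1 mean was 4.09 times a floor of 3 reads over the siNC group. The floor covers counting error in siNC only. Counting error of the 11 siAPE1 reads is left out, so 4.09 is no lower limit. One of 73 bases had 0, 0 and 4 reads in siNC and 8, 7 and 6 in siAPE1 (limma adjusted p = 0.0351), and its call was lost in 8 of 15 alternatives, whose adjusted p reached 0.238.

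Among 119 features with a mean of at least 500 TPM, 14 were higher and 24 lower, and the median log2 change was -0.22. Among 2993 features of 20 to 100 TPM, 693 were higher and 320 lower, with a median of 0.13. The 100 most abundant features held 30.7% ± 2.37 of the listed TPM in siNC and 25.8% ± 1.33 in siAPE1 (exact permutation test, two-sided p = 0.1, the smallest possible with 3 against 3). Of features shorter than 1000 bases, 105 were higher and 109 lower. Of those of 8000 to 16000 bases, 312 were higher and 77 lower. These counts by length include siNC replicate 2, without which the Spearman coefficient of fold change with length over features of at least 1000 bases went from 0.143 to 0.0139. The median recovered length was 5030 bases among higher, 3452 among lower and 4325 among tested features.

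Libraries of one group lay closer to each other than to the other group along the first principal component, which held 54.98% of the variance. By Spearman coefficient every pair within a group lay above every pair across groups. The lowest within a group was 0.964 (siNC replicates 2 and 3). The highest across groups was 0.956 (siNC replicate 3 and siAPE1 replicate 1). By the size of the differences this order did not always hold. The median absolute log2 difference was 0.318 between siNC replicates 2 and 3, and 0.311 between siNC replicate 3 and siAPE1 replicate 2. It was 0.106 to 0.273 for the other pairs within a group and up to 0.470 across groups. The second principal component held 17.8% and parted siNC replicate 2 from siNC replicates 1 and 3, with the siAPE1 libraries between them. The median SD between replicates was 0.21 on the log2 scale in siNC and 0.11 in siAPE1. No pair of libraries agreed within sampling noise, the closest being siAPE1 replicates 2 and 3, whose median chi-square was 2.44 times that expected from counting. Over features of at least 1000 bases, the deviation of siNC replicate 2 from the mean of the 6 libraries fell with length (Spearman coefficient across features -0.376), while the other 5 libraries had coefficients between 0.0419 and 0.155. Its median log2 deviation was 0.12 at 1000 to 2000 bases and -0.41 at 16000 bases or more, while features shorter than 1000 bases had a median of -0.15. Without siNC replicate 2, 2055 features were higher and 1148 lower.

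**Figure D4:**
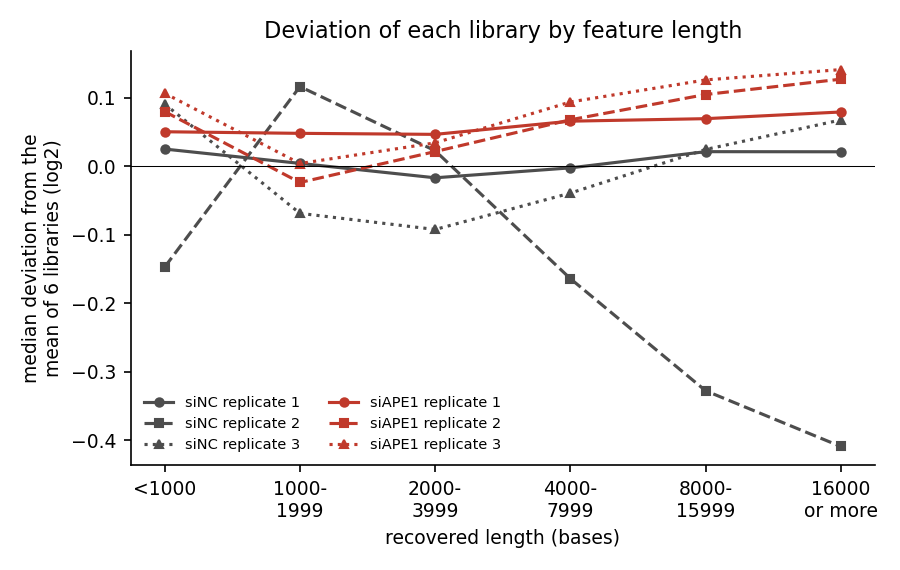
Median log2 deviation of each library from the mean of the 6 libraries, for tested features in 6 classes of recovered length in bases. Lines are libraries, grey for siNC and red for siAPE1, and siNC replicate 2 runs from 0.12 in the class that starts at 1000 bases to -0.41 at 16000 bases or more.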

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

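The alternatives with equal medians, with a length trend removed and with limma-voom on recovered reads were chosen after seeing the data. Main counts were 1717 higher and 830 lower features. Without the filter on low values the counts were 1098 and 512, over 19328 features tested, and against a 1.5-fold change they were 160 and 90. Equal medians gave 1137 and 1235, quantile normalization 1286 and 1310, and limma-voom on recovered reads 1418 and 1333, and these 3 recentre the libraries. Removing the length trend gave 1907 and 936. Omitting 1 library gave between 731 and 2055 higher features, the extremes being without siAPE1 replicate 3 and without siNC replicate 2, and between 393 and 1148 lower features, at the same extremes. Counts fell by more than 1.5 times without siAPE1 replicate 1 (979 and 494), replicate 2 (789 and 398) or replicate 3, and lower calls also without siNC replicate 1 (483). The cause was not tested. Of the 2547 calls, 250 were shared with the test against a 1.5-fold change. The other alternatives shared between 1110, without siAPE1 replicate 3, and 2534, with a pseudocount of 5.

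With the replicate block, 1241 features were higher and 574 lower. Deviations of libraries with the same number correlated at 0.00755, -0.0718 and 0.0826 for numbers 1, 2 and 3. The deviations of siNC replicate 2 correlated best with those of siAPE1 replicate 1 (0.1505). No pairing by number was seen. Deviations within a group of 3 are not independent, and those of siNC replicate 2 carry its length trend. They cannot exclude that the numbers mark a shared culture or day. The count models foreseen for a table of counts, their size factors and their count filters were not run, and limma-voom was the only model fitted to the recovered reads. Tests of APEX1 and of the gene lists gave no value under any setting because the features are unnamed. With 3 libraries per group, a simulation with 200 changed features recovered 9.33% of changes of 1.5-fold. The real data gave 2547 calls, which makes the Benjamini-Hochberg threshold less strict, so that share need not carry over. Features past no threshold are still not shown to be stable.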

Other observations

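The omission of siNC replicate 2 had been planned, and the other tests in this part, with the bounds set for each, were chosen after the result they bear on was seen. The real grouping of the 6 libraries gave 1717 higher and 830 lower features, and the highest count in one direction in any of the other splits into 3 and 3 was 1. Only 1 of the 10 splits, the real one, gave counts as large, but 10 splits cannot give a share under 0.05. Each of the other splits mixes both groups on each side, so any difference between the groups widens its spread and leaves few calls. The comparison therefore cannot tell siAPE1 from another difference between the groups.

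The identifiers and the values in the table did not belong together in the part that could be examined. Changed lengths in another annotation version are argued against, since 17.4% of the 23 identifiers had a recovered length within 20% of the exonic length. A candidate explanation is that the identifier column came from another table, or another order of features, than the values, and the Spearman coefficient of 0.154 between both lengths is what that would give. No biological explanation was tested.

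Among features of at least 1000 bases, the deviation of siNC replicate 2 fell with feature length, whereas the features under 1000 bases lay low as well (median log2 deviation -0.15). The Spearman coefficient was -0.376. That library also had the most recovered reads, 11189954, and its depth stays open. A weaker trend shared by the control siRNA group stays open: against the siAPE1 mean, siNC replicates 1 and 3 had coefficients of -0.0448 and 0.0136, inside the range of -0.169 to 0.103 that siAPE1 libraries showed against the others of their group. RNA integrity or fragment size of that 1 library also remains a possible explanation, for which no measure per library was used here. A biological difference of that sample stays open and untested.

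More features were higher than lower in siAPE1 on the TPM scale. The share of higher calls was 47.9% with equal medians, 49.5% after quantile normalization and 51.5% with limma-voom on the recovered reads. These settings recentre the libraries, so the excess depends on the choice of scale. The length trend of siNC replicate 2 is argued against as the whole cause, since 64.2% of the calls were still higher without that library. The median log2 difference of the tested features was 0.13 with that library and 0.08 without it. It was 0.12 with the length trend removed from each library. That removal kept the mean offset of each library, so the 0.12 cannot tell whether the trend moved the median. The 100 most abundant features held a lower share in siAPE1, and rescaling without them took the median log2 difference of the others from 0.131 to 0.0618. That drop follows from the lower share by arithmetic. It is no separate evidence for that share as a cause. A general rise in RNA per cell could not be tested, because TPM holds no absolute scale. An effect of siAPE1 itself stays open.

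Among 10872 features above 0 in all 6 libraries, 4587 had a recovered length that no other such feature had.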
